A study of Mus musculus with 14 samples.

How the data were processed

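Poly(A) RNA of whole spleens from 14 female BALB/c mice was sequenced from both ends of each fragment with reads of 150 bases on an Illumina HiSeq instrument after non-stranded library preparation, per the labels' protocols. The mice formed 4 groups: 3 with petrolatum vehicle, 4 with imiquimod cream on dorsal skin, 4 with imiquimod cream on the ear and 3 with IL-23 injected into the ear. The labels call the samples biological replicates and put all of them in 1 batch. Some replicate numbers are missing in the control and imiquimod groups, and whether mice or libraries were left out is not known.

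The deposited table holds 1 raw read count per gene and library, as the whole numbers in it show. The tools fastp 0.23.2, HISAT2 2.2.1, StringTie 2.2.1, featureCounts 2.0.3 of the Subread package and DESeq2 1.38.3 and the genome build GRCm39 are named without roles or settings, per the submitters' processing notes; how reads with several matches were counted, and the annotation, are not given in the sources used here. Of 22740 entries in the deposited count table, 624 are assembled loci without a gene name. They held 0.484% to 0.674% of each library's counts and were left out of library sizes and tests. The other 22116 comprise 22105 Ensembl genes, of which 22101 were found in GENCODE mouse release 39, and 11 Ensembl transcripts; 528 without a symbol were named from that annotation, and coordinates were taken from it. They comprise 21623 protein-coding, 262 immunoglobulin and 225 T cell receptor entries. Since the library kit marks no strand, reads of overlapping genes on opposite strands cannot be told apart. Among counts of 1 to 10, 58.2% to 60.9% were even in each library, against 49.1% to 50.7% among higher counts, so the low counts may not all be single fragments.

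Totals over named genes were 28354674 to 35086665 in the control, 35024011 to 40289411 in the imiquimod-dorsal, 34551193 to 37402120 in the imiquimod-ear and 33888595 to 35456180 in the IL-23-ear libraries. A gene with 0 counts may be present at up to 3 counts, or 0.0745 to 0.1058 CPM; this floor covers counting error only, since reads without molecular identifiers are not independent molecules. The 18 pairs of replicates differed by more than sampling noise, with a chi-square per degree of freedom of 24.1 to 141.4, so none was counted as a repeat of another.

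Genes were tested with edgeR 4.0.16 in R 4.3.3 by the robust quasi-likelihood F test with TMM scaling. Genes were kept by filterByExpr with a minimum count of 10, which left 15159. All 14 libraries entered 1 fit with 10 residual degrees of freedom and a common biological coefficient of variation of 18.7%, and p-values were adjusted over the 15159 genes after Benjamini and Hochberg, with a threshold of 0.05. Each adjusted p of a single gene is from this test unless another tool is named. Log2 fold changes are given with their SE, and CPM as mean ± SD of TMM-scaled values. The 5 comparisons were each treated group against control, imiquimod-ear against imiquimod-dorsal and IL-23-ear against imiquimod-ear; the latter pair test differences between treatments directly.

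Gene lists, 36 in all with 634 different genes of which 4 are in more than 1 list, were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01 for lists with at least 5 tested members. P-values were adjusted over the lists, and no list passed with the correlation estimated from the data. They cover type I interferon response, interferon gamma response, inflammatory cytokines and chemokines, the IL-17 and IL-23 axis, mature neutrophil, neutrophil progenitor, monocyte, red pulp macrophage, marginal zone macrophage, conventional and plasmacytoid dendritic cell, eosinophil, basophil and mast cell, erythroid, heme biosynthesis, megakaryocyte and platelet, hematopoietic stem and progenitor, cell cycle, B cell, marginal zone B cell, plasma cell, immunoglobulin heavy chain, germinal center, T cell, regulatory T cell and checkpoint, NK and cytotoxic, MHC class I and class II presentation, complement and Fc receptor, Toll-like receptor signaling, unfolded protein response, cholesterol synthesis, stromal and endothelial, pancreas, adipose, immediate early and heat shock, and mitochondrially encoded genes.

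The lists, tests, most alternatives and the rule for named genes were chosen before the data were examined. For each comparison the rule takes the 8 largest rises and 8 largest falls among called genes with a mean log2 CPM of at least 1 and groups that do not overlap, passing over predicted genes, pseudogenes and variable segments of immunoglobulins and T cell receptors. It adds the 2 called members with the smallest adjusted p of each list with at least 3 called members, and 20 genes named whatever their result. Some single-gene results under this rule are not reported here. Those alternatives were DESeq2 1.42.0, limma-voom, RLE size factors, haemoglobin and immunoglobulin genes taken out, no filter on low counts, only the groups compared, the replicate number as a block, a 2-fold minimum, and each replicate left out in turn. Chosen after seeing the data were the unnamed loci kept, the trend on exonic length removed (loess, span 0.5), the list tests without haemoglobin and immunoglobulin genes, and the correlations without each control. Tables were read with Python 3.11.15 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.

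The test was tried on simulated counts in which 200 of 15159 genes were changed, and 20 more were raised 1.5-fold as a list. All were drawn from genes above a minimum mean CPM, so the recovered shares do not cover genes of the lowest counts. Of 2-fold changes among the 200 the test recovered 74% for imiquimod-dorsal against control, 76% for imiquimod-ear against control, 68% for IL-23-ear against control, 76% for imiquimod-ear against imiquimod-dorsal and 77% for IL-23-ear against imiquimod-ear. Of 1.5-fold changes it recovered 46%, 42%, 39%, 57% and 42% in the same order, and the false share of calls was 3.7%, 9.3%, 5.1%, 4.7% and 6%. In each, 0 of 20 unchanged lists of random genes were called. The simulated genes varied independently, so this does not show how often lists of correlated genes would be called falsely. In the IL-23 comparison a change of 1.5-fold in a single gene would thus often be missed.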

Results

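Spleen RNA of 14 female BALB/c mice was sequenced after poly(A) selection to ask how the spleen differs between models of psoriasis-like skin inflammation. Petrolatum, given as the vehicle, had been put on the back and ears of 3 control mice, which the series' design text calls untreated. Imiquimod, an agonist of Toll-like receptor 7, had been given each day for 5 days as a 5% cream, on the back of 4 mice and on the ear of 4 others. IL-23, a cytokine that sustains type 17 T cells, had been injected into the ear skin of 3 mice at 1 µg per ear, as 4 injections over 7 days. The groups are called control, imiquimod-dorsal, imiquimod-ear and IL-23-ear below, and a library is named by its group and replicate number. Each mouse gave 1 library with 28354674 to 40289411 counts over named genes, and 15862 to 16375 genes had at least 1 count. The 4 imiquimod-dorsal libraries lay between 74.11 and 91.28 on the first principal component, which held 56.7% of the variance, and the 3 control libraries lay between -51.68 and -33.22. The IL-23-ear libraries lay among or beyond the controls, between -60.77 and -42.92, and 3 imiquimod-ear libraries lay between -4.94 and 4.42. Imiquimod-ear 5 lay at -30.98, beside control 5 at -33.22. Its Spearman correlation across genes was 0.9871, 0.9863 and 0.9873 with controls 2, 4 and 5. It was 0.9852 to 0.9875 with the IL-23-ear libraries and at most 0.9863 with another imiquimod-ear library.

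**Figure D1:**
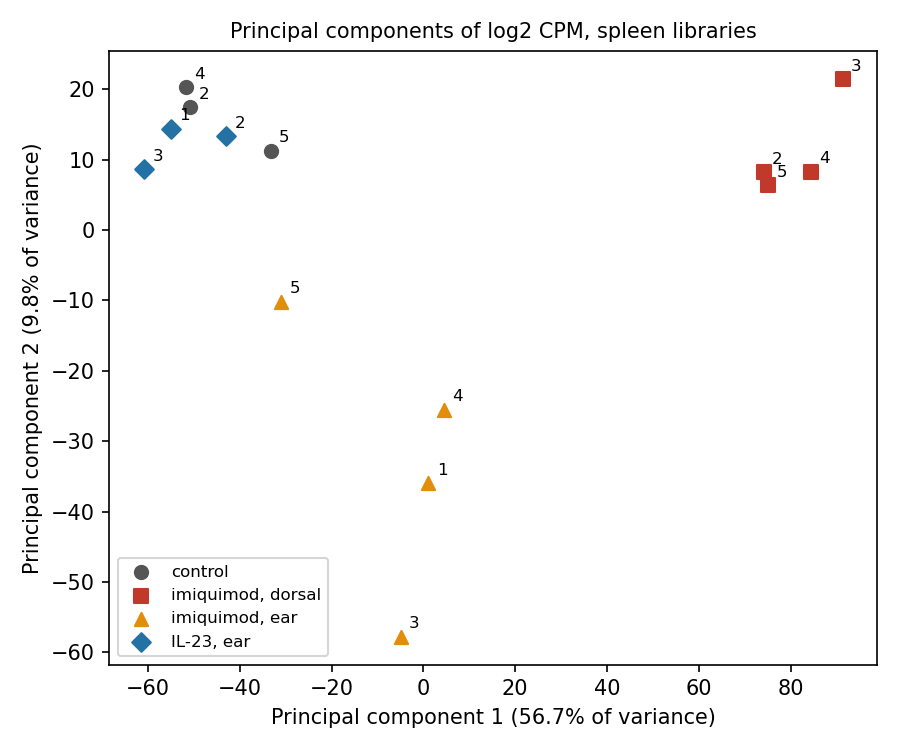
Principal components of log2 CPM of the 14 spleen libraries. Each point is 1 library, marked by group and replicate number, with component 1 (56.7% of the variance) on the horizontal and component 2 (9.8%) on the vertical axis, and the 4 imiquimod-dorsal libraries stand at 74.11 or more on component 1 while the other 10 libraries lie at 4.42 or less.

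Imiquimod on the back was compared with vehicle to find what the spleen does when a large area of skin is treated. Genes of red cell formation, cell division and neutrophils rose, and interferon-stimulated, T cell and NK cell genes fell. All 32 tested erythroid genes rose, with a median log2 fold change of 3.98, and all 30 cell cycle genes rose, with a median of 2.89. All 22 T cell genes fell, with a median of -2.54, and 28 of 29 type I interferon response genes fell, with a median of -2.84. Of 15159 genes tested with edgeR's quasi-likelihood test, 9071 (59.8%) changed: 4890 rose and 4181 fell, and 3002 of them changed by 2-fold or more. Here and below, rises and falls are relative to the other RNA of a library. Spleen size and cell numbers were not measured here, so a fall does not show a loss of cells.

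The erythroid list rose against the other genes (adjusted p = 1.16e-08, adjusted p = 0.503 with an estimated correlation). Its 32 members also passed when adjusted over the list alone. Tfrc, the transferrin receptor that brings iron into the cell, averaged 1750 ± 316 CPM (SD, n = 4) against 125 ± 26.1 (n = 3), a log2 fold change of 3.81 ± 0.41 (SE, adjusted p = 1.18e-05). Tspan33 rose by 3.50 ± 0.43 (adjusted p = 2.79e-05). Alas2, the erythroid enzyme that starts heme synthesis, rose by 2.38 ± 0.71 (adjusted p = 0.0128), a call lost without control 4 (2.21, adjusted p = 0.0518) or control 5 (2.05, adjusted p = 0.0582). All 11 heme biosynthesis genes rose, also adjusted over the list alone, with a median of 3.13 (adjusted p = 5.21e-06, adjusted p = 0.447 with an estimated correlation). Among them Tmem14c rose by 2.17 ± 0.18 (adjusted p = 1.33e-06) and Slc25a38, the mitochondrial glycine carrier, by 2.30 ± 0.22 (adjusted p = 3.48e-06). Haemoglobin genes took 8.55% ± 1.53 of the counts (SD, n = 4) against 2.45% ± 1.53 in the controls (n = 3).

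The largest rises included further genes of red cell precursors. Erfe (ENSMUSG00000047443; GRCm39 chromosome 1, 91294112 to 91302460, plus strand), which encodes erythroferrone, a hormone of erythroblasts that lowers hepcidin, went from 0.391 ± 0.439 to 49.8 ± 20.9 CPM, a log2 fold change of 6.92 ± 0.91 (adjusted p = 4.95e-05). Cdhr2 (ENSMUSG00000034918, chromosome 13, 54849271 to 54884475, plus strand), a cadherin known from the intestinal brush border, went from 0.25 ± 0.0397 to 38.8 ± 2.14 CPM. This was the largest rise under the naming rule, at 7.26 ± 0.72 (adjusted p = 5.22e-06). Apol11b (5.66), Plek2 (5.60), Tmed6 (5.54), Ighg2c (5.47) and the theta globin gene Hbq1a (5.38) were also among the 8 largest rises, with adjusted p from 3.04e-05 for Plek2 to 0.00431 for Hbq1a. Reads of Hbq1a and Apol11b can be shared with similar copies, so their values are uncertain. BALB/c mice are known to carry IgG2a where the reference strain has Ighg2c (chromosome 12, 113248945 to 113252552, minus strand), so the counts given to Ighg2c are uncertain as to isotype.

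Cell division and granulocyte genes moved the same way. Cell cycle genes rose (adjusted p = 4.91e-13, adjusted p = 0.447 with an estimated correlation), with 30 of 30 adjusted over the list alone. The proliferation marker Mki67 went from 168 ± 49.5 to 1810 ± 309 CPM, a log2 fold change of 3.43 ± 0.35 (adjusted p = 7.39e-06). Ndc80, of the kinetochore, rose by 2.14 ± 0.20 and Nusap1, of the spindle, by 3.04 ± 0.27. Of 22 mature neutrophil genes, 20 rose and 2 did not pass, over all genes and adjusted over the list alone, with a median of 3.04 (adjusted p = 4.08e-06, adjusted p = 0.447 with an estimated correlation). S100a8 and S100a9, the subunits of calprotectin, rose by 3.95 ± 0.66 and 3.74 ± 0.61, and Ly6g, the granulocyte surface marker, by 4.09 ± 0.77 (adjusted p = 0.000307, 0.000268 and 0.000642). The neutrophil progenitor list, of primary granule proteins, had 9 members that rose, 1 that fell and 2 that did not pass, also adjusted over the list alone (adjusted p = 0.0163, adjusted p = 0.619 with an estimated correlation). In it Mpo, myeloperoxidase, rose by 3.76 ± 0.59, Elane, neutrophil elastase, by 3.89 ± 0.59 and Fcnb by 4.14 ± 0.64 (adjusted p = 0.000204, 0.000136 and 0.000141).

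Interferon-stimulated genes fell, although the agent is an agonist of a receptor known to induce interferon. The type I interferon list fell (adjusted p = 2.91e-11, adjusted p = 0.447 with an estimated correlation; 28 of 29 adjusted over the list alone). Ifit3 (ENSMUSG00000074896; chromosome 19, 34560899 to 34566443, plus strand) and its near-identical neighbour Ifit3b, whose reads may be split between them, changed by -5.17 ± 0.60 and -5.28 ± 0.60 (adjusted p = 2.26e-05 and 1.88e-05), Ifit3 from 196 ± 105 to 5.45 ± 1.67 CPM. Mx1 and Mx2, antiviral GTPases, changed by -4.63 ± 0.49 and -4.66 ± 0.48, Oas2 by -4.77 ± 0.49, and Irf7, the regulator of interferon induction, by -4.19 ± 0.40, with adjusted p from 4.75e-06 to 1.03e-05. Ifi206 changed by -4.78 ± 0.35, Ifi208 by -4.73 ± 0.32 and Gbp10 by -4.61 ± 0.44, each of a family of similar genes. Isg15 had a smaller fall of -1.25 ± 0.40 (adjusted p = 0.0177), lost without control 4 (-1.07, adjusted p = 0.0614) or control 5 (-1.14, adjusted p = 0.0519), and with the replicate number as a block (-1.04, adjusted p = 0.0514). Of 19 interferon gamma response genes 16 fell, also adjusted over the list alone, with a median of -1.22 (adjusted p = 3.91e-05, adjusted p = 0.497 with an estimated correlation). Examples were Gbp4 at -2.39 ± 0.22 and the chemokine Cxcl10 at -2.62 ± 0.43 (adjusted p = 2.63e-06 and 0.000249).

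Lymphoid and antigen-presenting groups fell beside them. T cell genes fell together (adjusted p = 4.6e-13, adjusted p = 0.447 with an estimated correlation), with 22 of 22 adjusted over the list alone. The T cell receptor subunit Cd3e went from 120 ± 28.0 to 19.2 ± 4.53 CPM (-2.64 ± 0.23, adjusted p = 1.96e-06). Cd28 changed by -2.32 ± 0.16 (adjusted p = 5.62e-07). In the NK and cytotoxic list 15 of 19 fell, also adjusted over the list alone, where 1 other rose (median -1.74, adjusted p = 4.08e-06, adjusted p = 0.447 with an estimated correlation). Members that fell included Il2rb (-2.02), Eomes (-1.91) and the NK receptor Ncr1 (-1.78 ± 0.22, adjusted p = 1.68e-05). Conventional dendritic cell genes fell in 16 of 18 cases (median -1.32, adjusted p = 5.85e-06, adjusted p = 0.447 with an estimated correlation). Plasmacytoid dendritic cell genes fell in 9 of 14 with 2 that rose (median -0.54, adjusted p = 0.0153, adjusted p = 0.447 with an estimated correlation). Regulatory T cell and checkpoint genes fell in 11 of 14 (median -1.21, adjusted p = 6.15e-05, adjusted p = 0.447 with an estimated correlation). MHC class I presentation genes fell in 15 of 15 (median -0.79, adjusted p = 3.78e-06, adjusted p = 0.447 with an estimated correlation). These 4 lists had the same counts adjusted over the list alone. Among their members, Ccr7, the receptor that guides dendritic cells and T cells, changed by -1.50 ± 0.11, Siglech by -1.01 ± 0.17 and H2-T23 by -1.22 ± 0.11 (adjusted p = 5.62e-07, 0.000201 and 1.24e-06).

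Smaller falls were measured in 4 more lists. MHC class II presentation genes fell in 10 of 11 cases, also adjusted over the list alone (median -0.39, adjusted p = 0.00257, adjusted p = 0.503 with an estimated correlation). IL-17 and IL-23 axis genes fell in 9 of 16 cases and in 10 adjusted over the list alone (median -0.50, adjusted p = 0.0113, adjusted p = 0.447 with an estimated correlation). Ahr and Sox13 changed by -1.04 ± 0.15 and -1.02 ± 0.14, and Il23r was at -0.58 ± 0.44 (adjusted p = 0.273). Il17a had 0 counts in all 14 libraries, where 3 counts would be 0.0745 to 0.1058 CPM. Il17f, Il22, Csf2 and Trgv6 also had too few counts to test. The list result thus does not cover these genes in any comparison. In the stromal and endothelial list 13 of 21 members fell and 2 rose, or 14 and 2 adjusted over the list alone (median -0.51, adjusted p = 0.00566, adjusted p = 0.447 with an estimated correlation). The B cell list had 8 that fell, 2 that rose and 11 that did not pass, also adjusted over the list alone (median -0.19, adjusted p = 0.0153, adjusted p = 0.613 with an estimated correlation). Its call was lost without imiquimod-dorsal 3 (-0.13, adjusted p = 0.0555).

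The other 19 lists did not pass, although single members did. Their adjusted p was 0.0794 for germinal center genes (8 fell, 2 rose), 0.171 for adipose genes and 0.217 for marginal zone macrophage and for Toll-like receptor signaling genes. For stem and progenitor genes and for immunoglobulin heavy chain genes (5 rose, 1 fell, median 1.07) it was 0.249 in each. It was 0.25 for red pulp macrophage genes and 0.27 for mitochondrially encoded genes. It was 0.503 for monocyte, cholesterol synthesis, pancreas and immediate early and heat shock genes, 0.536 for eosinophil, basophil and mast cell genes, 0.681 for complement and Fc receptor genes, 0.692 for marginal zone B cell genes and 0.709 for megakaryocyte genes. It was 0.762 for inflammatory cytokines (median 0.04, test direction downward), 0.795 for unfolded protein response genes and 0.879 for plasma cell genes. Tlr7, the receptor of imiquimod, changed by -1.63 ± 0.17 (adjusted p = 5.49e-06) and the complement gene C4b by -1.69 ± 0.12 (adjusted p = 5.62e-07). The plasma cell genes Jchain (-0.18 ± 0.20) and Sdc1 (-0.05 ± 0.15) and the red pulp macrophage gene Cd5l (0.42 ± 0.25) did not pass (adjusted p = 0.464, 0.776 and 0.166). Of 9 tested pancreas genes 6 passed as higher, and imiquimod-dorsal 4 held nearly all of their counts: Ctrb1 was at 94.8 CPM there and at most 0.7 CPM in the other 13 libraries. The adipose marker Adipoq was highest in control 5, at 4.32 CPM.

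Imiquimod on the ear was compared with vehicle to see whether a small treated site is enough to change the spleen. Plasma cell, cell division and immature granulocyte genes rose, and interferon-stimulated genes fell. All 17 plasma cell genes rose, with a median log2 fold change of 1.46, as did all 30 cell cycle genes, with a median of 1.60. Of 29 type I interferon response genes 26 fell, with a median of -1.59. In all, 3219 of 15159 genes changed, 2161 up and 1058 down, 630 of them by 2-fold or more.

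Genes of antibody-secreting cells stood out. Plasma cell genes rose (adjusted p = 2.46e-14, adjusted p = 0.48 with an estimated correlation), with 17 of 17 adjusted over the list alone. Jchain, the joining chain of secreted IgM and IgA, was at 2710 ± 476 CPM (SD, n = 4) against 982 ± 176 (n = 3, log2 fold change 1.46 ± 0.21, adjusted p = 0.00209). Sdc1, or CD138, rose by 1.30 ± 0.15 and Fkbp11, a chaperone of secretory cells, by 2.37 ± 0.24 (adjusted p = 0.00078 and 0.000511). Of 8 immunoglobulin heavy chain genes 5 rose and 1 fell, or 6 and 1 adjusted over the list alone (median 2.09, adjusted p = 0.00227, adjusted p = 0.48 with an estimated correlation). Ighg2c rose by 6.16 ± 0.79, from 6.09 ± 2.53 to 434 ± 358 CPM, Ighg2b by 3.18 ± 0.43 and Ighm by 1.39 ± 0.16 (adjusted p = 0.00175, 0.00182 and 0.00078). The constant genes are similar enough to share reads. Immunoglobulin genes took 3.77% ± 0.61 of the counts against 1.69% ± 0.14 in the controls. In the germinal center list 7 of 16 rose, also adjusted over the list alone (median 0.76, and 0.45 without imiquimod-ear 3, adjusted p = 0.0117, adjusted p = 0.514 with an estimated correlation). Unfolded protein response genes rose in 13 of 16 cases, or 14 adjusted over the list alone (median 0.62, adjusted p = 7.2e-07, adjusted p = 0.48 with an estimated correlation). Xbp1, a driver of the secretory program, rose by 1.28 ± 0.18 and Pdia4 by 1.14 ± 0.18 (adjusted p = 0.00175 and 0.00291).

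Cell cycle genes rose (adjusted p = 1.04e-15, adjusted p = 0.48 with an estimated correlation), with 30 of 30 adjusted over the list alone. Mki67 rose by 1.72 ± 0.33 and Cdc20 by 1.95 ± 0.31 (adjusted p = 0.00528 and 0.00296). Of 12 neutrophil progenitor genes 9 rose, or 10 with 1 that fell adjusted over the list alone (median 2.84, adjusted p = 0.000339, adjusted p = 0.48 with an estimated correlation). Elane (3.08 ± 0.57), Prtn3 (3.07 ± 0.60), Fcnb (3.05 ± 0.62), Ctsg (3.00 ± 0.59) and Mpo (2.89 ± 0.57) were all among the 8 largest rises, with adjusted p from 0.00499 to 0.0064. Mature neutrophil genes rose in 9 of 22 cases, or 10 adjusted over the list alone (median 0.83, adjusted p = 0.025, adjusted p = 0.629 with an estimated correlation). The call was lost without imiquimod-ear 1 (0.57, adjusted p = 0.066) or imiquimod-ear 5 (0.72, adjusted p = 0.101), and with the trend on gene length removed (0.76, adjusted p = 0.0671). S100a8 rose by 2.22 ± 0.61 (adjusted p = 0.025), lost without control 2, control 4, control 5 or imiquimod-ear 1 (adjusted p = 0.0948, 0.1, 0.0587 and 0.0582). S100a9 rose by 2.06 ± 0.56 (adjusted p = 0.0249), lost without control 2, control 4 or imiquimod-ear 1 (adjusted p = 0.1, 0.106 and 0.0583). Ly6g did not pass at 2.01 ± 0.73 (adjusted p = 0.0706). In imiquimod-ear 3, S100a8 was at 16.9 CPM, against a mean of 12.7 ± 1.25 CPM in the controls and of 59.1 ± 28.5 CPM over the 4 imiquimod-ear libraries.

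The type I interferon list fell here too (adjusted p = 1.04e-15, adjusted p = 0.48 with an estimated correlation; 27 of 29 adjusted over the list alone). Ifit3b changed by -2.62 ± 0.52, Ifit3 by -2.58 ± 0.54, Mx2 by -2.23 ± 0.42 and Irf7 by -1.94 ± 0.37, with adjusted p from 0.00527 to 0.00777. Ifit1 fell by 2.13 ± 0.47, a call lost without control 4 (-1.73, adjusted p = 0.0539). Outside the list, Ifi213 (-2.36), Ifi206 (-2.32), Trim30c (-2.20) and Ifi208 (-2.09) were among the largest falls. Isg15 did not pass at -1.03 ± 0.40 (adjusted p = 0.0886). Interferon gamma response genes fell in 10 of 19 cases, or 11 adjusted over the list alone (median -0.78, adjusted p = 4.67e-06, adjusted p = 0.48 with an estimated correlation). Gbp4 fell by 1.07 ± 0.21, while the fall of Cxcl10 (-1.26 ± 0.41, adjusted p = 0.0484) was lost without control 4, control 5, imiquimod-ear 1, imiquimod-ear 3 or imiquimod-ear 4 (adjusted p = 0.161, 0.118, 0.0802, 0.117 and 0.079).

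Lymphoid and presenting cell lists fell by little. T cell genes fell with a median of -0.37, and -0.62 without imiquimod-ear 5 (adjusted p = 2.38e-05, adjusted p = 0.514 with an estimated correlation). Of its members 4 of 22 passed singly, also adjusted over the list alone, and Cd3e did not (-0.40 ± 0.22, adjusted p = 0.215). Conventional dendritic cell genes (median -0.39, 2 of 18 fell, 0 adjusted over the list alone, adjusted p = 0.000121) had adjusted p = 0.48 with an estimated correlation. Toll-like receptor signaling genes (median -0.12, and -0.19 without control 2, 3 of 18 on both counts, adjusted p = 0.00507) and IL-17 and IL-23 axis genes (median -0.31, 3 of 16 on both counts, adjusted p = 0.0254) also had adjusted p = 0.48 with an estimated correlation. The axis call was lost without control 2, imiquimod-ear 4 or imiquimod-ear 5 (adjusted p = 0.0678, 0.0532 and 0.0601), and Il23r was at -0.71 ± 0.44 (adjusted p = 0.265). Tlr7 fell by 0.76 ± 0.17 (adjusted p = 0.00888), lost without control 4 (-0.63, adjusted p = 0.0513). B cell genes (7 of 21 fell and 2 rose, or 8 and 2 adjusted over the list alone, median -0.16, adjusted p = 0.00687) and MHC class II presentation genes (3 of 11 on both counts, median -0.12, and -0.23 without imiquimod-ear 5, adjusted p = 0.00718) each had adjusted p = 0.514 with an estimated correlation. MHC class I presentation genes fell in 4 of 15 cases on both counts (median -0.21, adjusted p = 0.00227, adjusted p = 0.541 with an estimated correlation). In the NK and cytotoxic list 3 of 19 fell on both counts (median -0.35, and -0.54 without imiquimod-ear 5, adjusted p = 0.00244, adjusted p = 0.53 with an estimated correlation). That call was lost without control 5 (adjusted p = 0.0519). Ncr1 did not pass (-0.54 ± 0.22, adjusted p = 0.0962), and Siglech fell by 0.81 ± 0.17 (adjusted p = 0.00679). The plasmacytoid dendritic cell list, to which Siglech belongs, did not pass (2 of 14 fell and 1 rose on both counts, median -0.22, adjusted p = 0.174, adjusted p = 0.514 with an estimated correlation).

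The remaining lists that passed moved by small amounts or rested on few libraries. Cholesterol synthesis genes rose in 6 of 18 cases, or 10 adjusted over the list alone (median 0.38, and 0.25 without imiquimod-ear 1, adjusted p = 0.00244, adjusted p = 0.554 with an estimated correlation). Mitochondrially encoded genes rose in 7 of 13 on both counts (median 0.19, and 0.12 without imiquimod-ear 5, adjusted p = 0.000372, adjusted p = 0.485 with an estimated correlation). The mitochondrial call was lost when the trend on gene length was removed (median -0.004, adjusted p = 0.787). Red pulp macrophage genes fell in 4 of 21 cases on both counts (median -0.31, and -0.19 without imiquimod-ear 3, adjusted p = 0.0039, adjusted p = 0.541 with an estimated correlation). Cd5l was at -0.11 ± 0.25 (adjusted p = 0.78). Marginal zone macrophage genes had 2 of 7 that fell and 1 that rose, or 4 and 1 adjusted over the list alone (median -0.76, adjusted p = 0.0255, adjusted p = 0.485 with an estimated correlation). This was lost without control 5, imiquimod-ear 3 or imiquimod-ear 5 (adjusted p = 0.0585, 0.0618 and 0.0575). Megakaryocyte genes rose as a list with 0 of 18 passing singly on either count (median 0.70, adjusted p = 0.0075, adjusted p = 0.629 with an estimated correlation). This was lost without control 4 (0.37, adjusted p = 0.103) or imiquimod-ear 5 (0.54, adjusted p = 0.0713). Stromal and endothelial genes fell in 5 of 21 cases, or 6 adjusted over the list alone (median -0.18, adjusted p = 0.023, adjusted p = 0.514 with an estimated correlation). The call was lost without control 5 (-0.11, adjusted p = 0.0816), and the medians were -0.27, -0.09, -0.09 and -0.30 without control 4 and imiquimod-ear 1, 4 and 5. Adipose genes fell in 2 of 10 cases on both counts (median -1.52, adjusted p = 0.0411, adjusted p = 0.554 with an estimated correlation). The call was lost without control 4, control 5 and imiquimod-ear 1, 3 and 5, with a median of -0.58 and adjusted p = 0.621 without control 5.

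Erythroid genes did not pass as a list after ear treatment: the median was 0.88, 0 of 32 members passed on either count, and the adjusted p was 0.174. Alas2 was at 0.07 ± 0.66 (adjusted p = 0.95), and haemoglobin took 2.31% ± 1.80 of the counts. Without imiquimod-ear 4 the erythroid median was 0.16 (adjusted p = 0.81), and without imiquimod-ear 3 it was 1.11 and the list passed. It also passed with the replicate block (0.85, adjusted p = 0.00816). The count of changed genes moved with single libraries: it was 1406 without control 2, 1090 without control 4, 1912 without imiquimod-ear 1, 1976 without imiquimod-ear 3 and 4976 without imiquimod-ear 5. With only the libraries of these groups in the fit it was 1046.

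**Figure D2:**
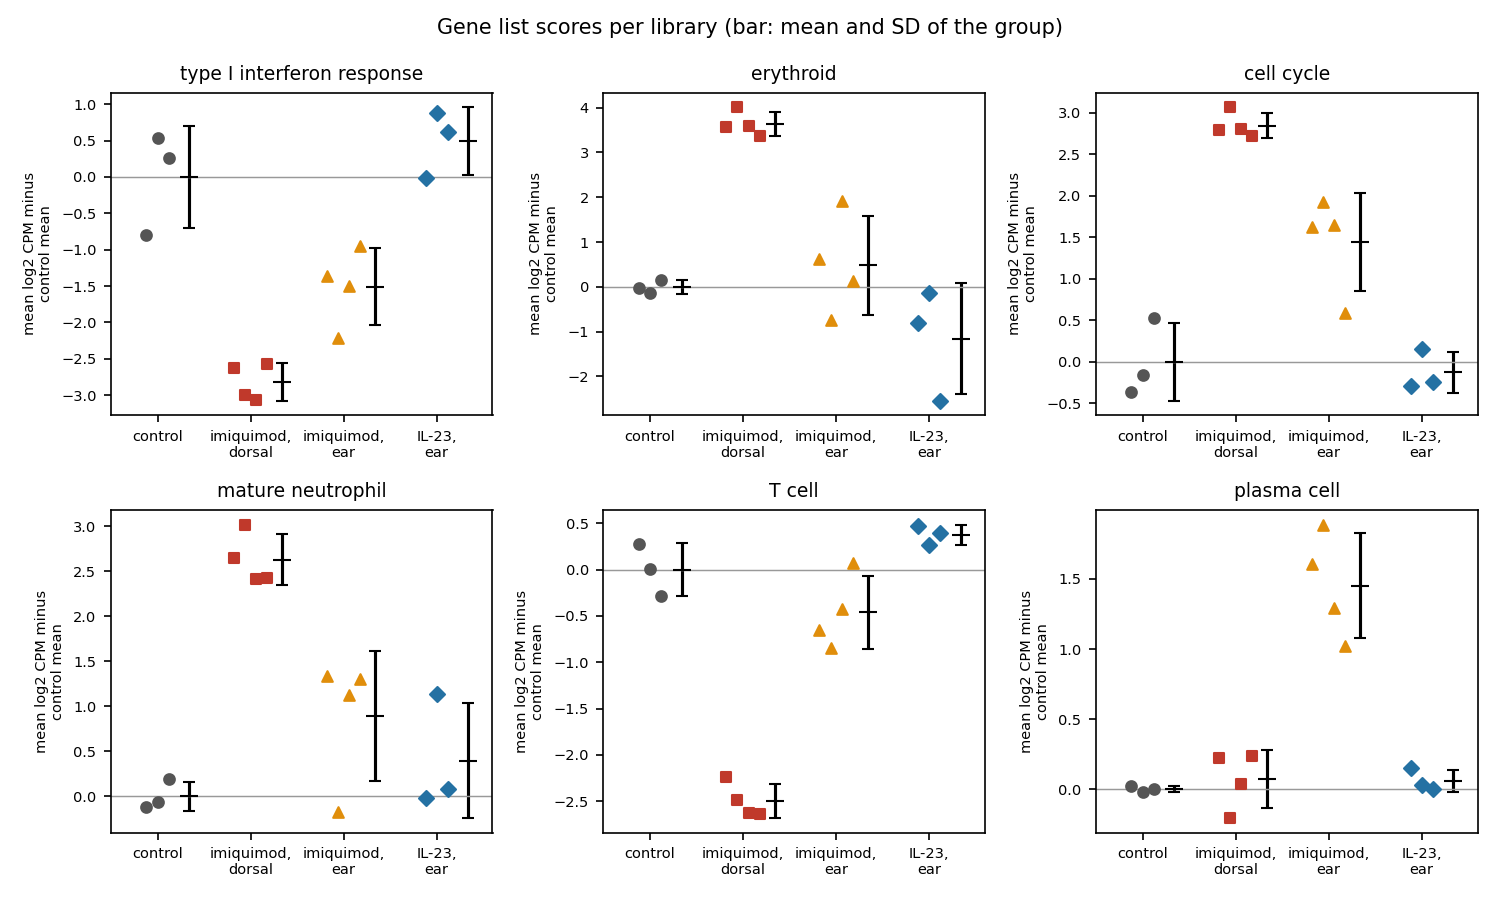
Scores of 6 gene lists in each of the 14 libraries. The vertical axis is the mean log2 CPM of a list's genes minus the control mean, points are libraries, and black bars give the mean and SD of the group, and the type I interferon score lies between -3.072 and -2.57 in the imiquimod-dorsal libraries, between -2.214 and -0.947 in the imiquimod-ear libraries and between -0.792 and 0.531 in the controls.

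IL-23 injected into the ear skin was compared with the petrolatum controls to see whether the spleen changes in this model. No injected vehicle group is among the samples, so the comparison covers the injections as well as the cytokine. Few genes differed: 8 of 15159 passed, 7 up and 1 down, by less than 2-fold. The 7 that rose encode ribosomal proteins and mitochondrial respiratory subunits. Rps14 (chromosome 18, 60880152 to 60911630, plus strand) went from 725 ± 24.8 to 985 ± 18.2 CPM (SD, n = 3 in each group), a log2 fold change of 0.44 ± 0.06. mt-Co2, a subunit of cytochrome oxidase, went from 1880 ± 114 to 2510 ± 25.4 CPM (0.42 ± 0.06). mt-Nd3 (0.40 ± 0.06), mt-Atp6 (0.40 ± 0.06), mt-Co3 (0.36 ± 0.05), Rps15 (0.34 ± 0.05) and Rps24 (0.33 ± 0.05) rose by similar amounts. Phykpl (chromosome 11, 51475574 to 51495323, plus strand), a lysine-degrading enzyme, fell by 0.76 ± 0.12. All 8 had adjusted p = 0.045, and each call was lost without any 1 of the 6 libraries, with an adjusted p of up to 0.351. By edgeR, 0 genes passed without control 2, control 4 or IL-23-ear 1, 2 or 3 (867, 978, 1280, 1031 and 782 at an unadjusted p under 0.05), and 1 passed without control 5. Of the tools, DESeq2 called 132 genes and limma-voom 15, and 1305 genes had an unadjusted p under 0.05. Reads of ribosomal protein genes can come from their many processed copies, so those 3 values are uncertain. The ribosomal protein genes also had a median above the controls after imiquimod at both sites, so their rise was not particular to IL-23.

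As a group, the mitochondrially encoded genes rose: 4 of 13 passed singly and 12 adjusted over the list alone, with a median of 0.33 (adjusted p = 3.64e-20, adjusted p = 0.146 with an estimated correlation). The other 7 lists that passed had 0 members that passed, over all genes or adjusted over the list alone, and each had adjusted p = 0.973 with an estimated correlation. Erythroid genes were lower in 32 of 32 cases (median -0.92, adjusted p = 5.82e-11), with a median of -1.53 without IL-23-ear 2 and -0.49 without IL-23-ear 3, and haemoglobin took 0.96% ± 0.56 of the counts (n = 3). T cell genes were higher in 22 of 22 cases (median 0.33, adjusted p = 1.89e-06). Type I interferon genes were higher in 28 of 29 cases (median 0.41, adjusted p = 0.000258), but the call was lost without control 2 (0.14, adjusted p = 0.495). The median was 0.68 without control 4 and 0.19 without IL-23-ear 2. Unfolded protein response genes had a median of 0.23 (adjusted p = 0.00154), with 0.11 without control 2 and 0.36 without control 5. Their call was lost with the replicate block (0.16, adjusted p = 0.175). Immediate early and heat shock genes had a median of 0.39 (adjusted p = 0.00142), with 0.23 without control 2 and 0.12 (adjusted p = 0.0654) without IL-23-ear 3, where Hspa1a was at 106 CPM and at most 14.2 CPM elsewhere. MHC class I genes (median 0.22, adjusted p = 0.00321) lost the call without control 2 (0.13, adjusted p = 0.202). MHC class II genes (median 0.16, adjusted p = 0.00562) lost it without control 5 (0.13, adjusted p = 0.132) or IL-23-ear 2 (0.13, adjusted p = 0.062), and with the trend on gene length removed (0.11, adjusted p = 0.158).

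Single genes tied to the cytokine and to inflammation did not pass. The mature neutrophil list did not pass either (median 0.53, adjusted p = 0.12), but it did with the replicate block (0.54, adjusted p = 0.0151) and with only these groups in the fit (0.51, adjusted p = 0.0311). The interferon gamma list (median 0.17, adjusted p = 0.331) passed with the block (0.31, adjusted p = 0.0141). Il23r, of the IL-23 receptor, was at 0.35 ± 0.45 (adjusted p = 0.881), and the IL-17 and IL-23 axis list had an adjusted p of 0.573. That result leaves out Il17a, Il17f and Il22, which had too few counts to test. S100a8 (1.05 ± 0.62), S100a9 (0.86 ± 0.57), Ly6g (1.12 ± 0.78) and Mpo (0.19 ± 0.56) had adjusted p from 0.705 to 0.949. Isg15 (0.62 ± 0.43), Irf7 (0.47 ± 0.39), Cxcl10 (0.57 ± 0.44) and Tlr7 (0.20 ± 0.18) had adjusted p from 0.753 to 0.817. Alas2 (-1.49 ± 0.72) and Mki67 (-0.34 ± 0.33) had adjusted p of 0.629 and 0.834. Cd3e (0.44 ± 0.24), Ncr1 (0.02 ± 0.23), Jchain (-0.05 ± 0.22), Sdc1 (-0.17 ± 0.16), Cd5l (-0.23 ± 0.27) and Siglech (-0.16 ± 0.18) had adjusted p from 0.662 to 0.995.

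The ear and dorsal treatments were compared directly to test whether their responses differ. The treated area differs with the site, so site, area and amount of cream cannot be told apart. The ear libraries had more T cell, plasma cell and interferon-stimulated RNA than the dorsal libraries, and less erythroid, heme, cell cycle and mature neutrophil RNA. T cell genes were higher in 21 of 22 cases, with a median log2 difference of 2.16, and erythroid genes were lower in 32 of 32, with a median of -2.995. Of 15159 genes 7237 differed, 3528 higher and 3709 lower after ear treatment, 2088 by 2-fold or more.

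Lymphoid and presenting cell lists were among those higher after ear treatment. T cell genes had adjusted p = 1.92e-14 (adjusted p = 0.495 with an estimated correlation), with 22 of 22 adjusted over the list alone. They included Il7r, the IL-7 receptor chain of resting T cells (chromosome 15, 9505874 to 9530262, minus strand), at 90.6 ± 24.4 against 13.3 ± 1.92 CPM (SD, n = 4 in each group, 2.77 ± 0.22, adjusted p = 2.86e-06), and Cd3e at 2.24 ± 0.22. Dapl1 (2.89 ± 0.31), Crisp3 (3.04 ± 0.39) and Scg5 (2.99 ± 0.42) were among the 8 largest rises. Regulatory T cell and checkpoint genes were higher in 13 of 14 cases on both counts (median 1.63, adjusted p = 9.16e-07, adjusted p = 0.495 with an estimated correlation). NK and cytotoxic genes were higher in 14 of 19, or 15 with 1 lower adjusted over the list alone (median 1.29, adjusted p = 6.1e-06, adjusted p = 0.495 with an estimated correlation). Plasma cell genes were higher in 15 of 17, or 16 (median 1.49, adjusted p = 2.44e-08, adjusted p = 0.495 with an estimated correlation). The immunoglobulin heavy chain list did not pass (2 of 8 higher on both counts, median 0.75, adjusted p = 0.368, adjusted p = 0.755 with an estimated correlation). Germinal center genes were higher in 11 of 16, or 12 adjusted over the list alone (median 1.46, and 0.90 without imiquimod-ear 3, adjusted p = 5.7e-05, adjusted p = 0.495 with an estimated correlation). Conventional dendritic cell genes were higher in 12 of 18, or 12 with 1 lower (median 0.81, adjusted p = 0.00038, adjusted p = 0.495 with an estimated correlation). Plasmacytoid dendritic cell genes were higher in 8 of 14 with 2 lower, on both counts (median 0.61, adjusted p = 0.0138, adjusted p = 0.495 with an estimated correlation). MHC class I genes were higher in 14 of 15 cases, or 15 adjusted over the list alone (median 0.63, adjusted p = 6.1e-06, adjusted p = 0.5 with an estimated correlation). The genes Ncr1 (1.24 ± 0.21), Jchain (1.64 ± 0.20) and Sdc1 (1.36 ± 0.14) passed, and Siglech (0.21 ± 0.16, adjusted p = 0.312) did not.

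Interferon-stimulated genes lay between the dorsal and control levels in the ear libraries. In the type I interferon list 21 of 29 were higher after ear treatment on both counts (median 1.28, adjusted p = 2.85e-06, adjusted p = 0.644 with an estimated correlation). Oas2 was higher by 2.94 ± 0.45 and Irf7 by 2.25 ± 0.36 (adjusted p = 0.000306 and 0.000345), while Isg15 did not differ past the threshold (0.22 ± 0.37, adjusted p = 0.651). Interferon gamma response genes were higher in 11 of 19 cases with 1 lower, on both counts (median 0.72, adjusted p = 0.0147, adjusted p = 0.674 with an estimated correlation). Cxcl10 was higher by 1.36 ± 0.40 (adjusted p = 0.0156), and outside the lists Gbp10 was higher by 2.73 ± 0.41 and Tlr7 was higher by 0.87 ± 0.16. Unfolded protein response genes (13 of 16 higher and 2 lower on both counts, median 0.66, adjusted p = 0.00146, adjusted p = 0.644 with an estimated correlation) were higher. So were cholesterol synthesis genes (13 of 18 higher and 1 lower on both counts, median 0.50, adjusted p = 0.00337, adjusted p = 0.672 with an estimated correlation). MHC class II genes were higher in 6 of 11 on both counts (median 0.23, adjusted p = 0.0363, adjusted p = 0.672 with an estimated correlation). The call was lost without imiquimod-dorsal 3 (adjusted p = 0.0673) or imiquimod-ear 5 (adjusted p = 0.0925).

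Of the lists that had risen after dorsal treatment, 4 were lower after ear treatment. The neutrophil progenitor list did not pass (median -0.82, 0 of 12 lower and 1 higher on both counts, adjusted p = 0.305, adjusted p = 0.818 with an estimated correlation). Erythroid genes (adjusted p = 3.1e-11), heme biosynthesis genes (11 of 11 lower, median -2.49, adjusted p = 2.2e-07) and mature neutrophil genes (19 of 22 lower, or 21 adjusted over the list alone, median -1.71, adjusted p = 9.46e-07) each had adjusted p = 0.495 with an estimated correlation. The counts of the first pair were the same adjusted over the list alone. Tfrc differed by -2.92 ± 0.35 and Alas2 by -2.31 ± 0.64 (adjusted p = 4.69e-05 and 0.011). Erfe (-5.08 ± 0.70), Cdhr2 (-4.34 ± 0.51), Plek2 (-3.97 ± 0.56), Tnip3 (-3.70 ± 0.31), Apol8 (-3.65 ± 0.72) and Nrip3 (-3.54 ± 0.48) were among the largest falls, with adjusted p from 2.19e-06 to 0.00159. Hbq1a was lower by -4.95 ± 1.13, and by -3.26 without imiquimod-dorsal 4. Cell cycle genes were lower in 29 of 30 cases, or 30 adjusted over the list alone (median -1.28, adjusted p = 7.85e-10, adjusted p = 0.534 with an estimated correlation). Mki67 was lower by -1.72 ± 0.29. S100a9 (-1.68 ± 0.50, adjusted p = 0.016) and Ly6g (-2.08 ± 0.61, adjusted p = 0.0142) were lower, as was S100a8 (-1.73 ± 0.53, adjusted p = 0.0184), whose call was lost without imiquimod-dorsal 3 (-1.48, adjusted p = 0.055). The call of Ly6g was lost with the replicate block (-1.91, adjusted p = 0.0638). Mpo (-0.87 ± 0.47), Cd5l (-0.54 ± 0.23) and Il23r (-0.13 ± 0.42) did not pass (adjusted p = 0.149, 0.0752 and 0.821). The muscle genes Mybpc2 (3.56) and Tnni2 (3.11) had the largest rises under the naming rule and were at 71 and 74.5 CPM in imiquimod-ear 4. Without that library the differences were 0.87 (adjusted p = 0.0312) and 0.40 (adjusted p = 0.0959). The call of Tnni2 was also lost without imiquimod-dorsal 2, 3 or 4 (adjusted p = 0.0508, 0.06 and 0.056).

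IL-23 and imiquimod at the ear were compared directly to test whether the 2 ear models differ. They differ in agent, and also in route and schedule. IL-23-ear libraries held more interferon-stimulated and T cell RNA and less plasma cell and cell cycle RNA than imiquimod-ear libraries. The erythroid list was lower too, but only 2 of 32 members passed over all genes. Its median moved from -1.63 to -0.97 without imiquimod-ear 4. Of 29 type I interferon genes 27 were higher, with a median log2 difference of 1.98, and all 17 plasma cell and all 30 cell cycle genes were lower, with medians of -1.47 and -1.83. Of 15159 genes 2623 differed, 1070 higher and 1553 lower after IL-23, 736 by 2-fold or more.

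The type I interferon list had adjusted p = 1.18e-21 (adjusted p = 0.388 with an estimated correlation), with 28 of 29 adjusted over the list alone. It included Ifit3 at 281 ± 117 CPM (SD, n = 3) against 32.8 ± 22.0 (n = 4), a difference of 3.10 ± 0.54 (adjusted p = 0.00429). Ifit3b (3.15 ± 0.53), Ifit1 (2.71 ± 0.48), Mx2 (2.63 ± 0.42), Oas2 (2.50 ± 0.44) and Irf7 (2.41 ± 0.37) were higher as well. So were Ifi206 (2.73 ± 0.31), Ifi213 (2.70 ± 0.35) and Ifit1bl1 (2.45 ± 0.36), with adjusted p from 0.000845 to 0.00431. Isg15 was higher by 1.65 ± 0.40 (adjusted p = 0.0181), lost without imiquimod-ear 1, IL-23-ear 2 or IL-23-ear 3 (adjusted p = 0.0512, 0.0635 and 0.0518). Interferon gamma response genes were higher in 11 of 19 cases, or 12 adjusted over the list alone (median 0.89, adjusted p = 6.7e-08, adjusted p = 0.388 with an estimated correlation). Cxcl10 was higher by 1.83 ± 0.41 (adjusted p = 0.0129). T cell genes were higher in 18 of 22 cases, or 22 adjusted over the list alone (median 0.83, adjusted p = 3.46e-12, adjusted p = 0.388 with an estimated correlation). Cd3e was higher by 0.85 ± 0.22 (adjusted p = 0.0225), lost without imiquimod-ear 1, imiquimod-ear 3, IL-23-ear 1 or IL-23-ear 3 (adjusted p = 0.0645, 0.0597, 0.0685 and 0.0714).

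Antibody and division genes were lower after IL-23. Plasma cell genes (adjusted p = 2.46e-15), cell cycle genes (adjusted p = 4.09e-19) and immunoglobulin heavy chain genes (5 of 8 lower and 1 higher on both counts, median -1.63, adjusted p = 0.00126) each had adjusted p = 0.388 with an estimated correlation. The counts of the first pair were the same adjusted over the list alone. Ighg2c differed by -6.38 ± 0.80, Ighg2b by -3.47 ± 0.44, Tmed6 by -4.24 ± 0.85, Nuggc by -2.96 ± 0.60 and Trabd2b by -2.77 ± 0.53, with adjusted p from 0.00115 to 0.00712. Jchain (-1.51 ± 0.21), Sdc1 (-1.47 ± 0.15) and Mki67 (-2.06 ± 0.33) were lower (adjusted p = 0.00158, 0.000483 and 0.00259). Neutrophil progenitor genes were lower in 6 of 12 cases, or 7 adjusted over the list alone (median -1.91, and -3.21 without IL-23-ear 2, adjusted p = 0.000299, adjusted p = 0.388 with an estimated correlation). Prtn3 was at -2.94 ± 0.60, Ctsg at -2.90 ± 0.58 and Mpo at -2.70 ± 0.56 (adjusted p = 0.00816, 0.00723 and 0.00929). The calls of Prtn3 and Mpo were lost with only these groups in the fit (adjusted p = 0.0526 and 0.0615). S100a8 (-1.17 ± 0.58), S100a9 (-1.20 ± 0.54) and Ly6g (-0.90 ± 0.68) did not pass (adjusted p = 0.184, 0.147 and 0.381). Erythroid genes were lower in 2 of 32 cases, or 26 adjusted over the list alone (median -1.63, and -0.97 without imiquimod-ear 4, adjusted p = 8.07e-08, adjusted p = 0.472 with an estimated correlation). Heme biosynthesis genes were lower in 2 of 11, or 6 adjusted over the list alone (median -0.84, and -0.45 without imiquimod-ear 4, adjusted p = 0.00643, adjusted p = 0.472 with an estimated correlation). Unfolded protein response genes were lower in 9 of 16, or 10 with 1 higher adjusted over the list alone (median -0.49, adjusted p = 0.000263, adjusted p = 0.472 with an estimated correlation). Cholesterol synthesis genes were lower in 6 of 18, or 10 adjusted over the list alone (median -0.39, and -0.24 without imiquimod-ear 1, adjusted p = 0.000263, adjusted p = 0.472 with an estimated correlation). Alas2 (-1.55 ± 0.69) did not pass (adjusted p = 0.14).

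Differences were also seen in 13 more lists. Higher after IL-23, with adjusted p = 0.388 with an estimated correlation in each, were MHC class I (9 of 15, or 11 adjusted over the list alone, median 0.43, adjusted p = 1.19e-06), MHC class II (6 of 11, or 9, median 0.28, adjusted p = 1.29e-05) and conventional dendritic cell genes (6 of 18, or 7, median 0.36, adjusted p = 0.000263). So were immediate early and heat shock (5 of 16, or 6, median 0.48, adjusted p = 0.00111), Toll-like receptor signaling (3 of 18 on both counts, median 0.17, adjusted p = 0.00343) and marginal zone macrophage genes (3 of 7 on both counts, median 1.01, adjusted p = 0.00869). NK and cytotoxic genes (4 of 19, or 5 adjusted over the list alone, median 0.49, adjusted p = 0.00118, adjusted p = 0.472 with an estimated correlation) were higher, as were mitochondrially encoded genes (4 of 13 on both counts, median 0.12, adjusted p = 0.00118, adjusted p = 0.462 with an estimated correlation). Megakaryocyte genes were lower (1 of 18, or 0 adjusted over the list alone, median -0.78, adjusted p = 0.00175, adjusted p = 0.518 with an estimated correlation). B cell genes (6 of 21 higher and 2 lower, or 8 and 2 adjusted over the list alone, median 0.12, adjusted p = 0.0284, adjusted p = 0.5 with an estimated correlation) and complement genes (7 of 16 on both counts, median 0.17, adjusted p = 0.0273, adjusted p = 0.5 with an estimated correlation) were higher. Germinal center genes were lower (6 of 16, or 7, median -0.55, adjusted p = 0.0273, adjusted p = 0.5 with an estimated correlation). The B cell, complement and germinal center calls were each lost without IL-23-ear 2 (adjusted p = 0.0802, 0.0883 and 0.0808). The complement call was also lost without imiquimod-ear 3 (adjusted p = 0.141), and its median was 0.29 without imiquimod-ear 1, 0.33 without IL-23-ear 1 and 0.11 without IL-23-ear 2. Red pulp macrophage genes were higher (4 of 21 on both counts, median 0.20, adjusted p = 0.0192, adjusted p = 0.536 with an estimated correlation). The call was lost without imiquimod-ear 3 (0.10, adjusted p = 0.158) or IL-23-ear 2 (0.17, adjusted p = 0.076), with 0.37 without imiquimod-ear 5. Tlr7 was higher by 0.96 ± 0.17 (adjusted p = 0.00349) and Siglech by 0.65 ± 0.17 (adjusted p = 0.0223), the latter lost without IL-23-ear 1 or IL-23-ear 2 (adjusted p = 0.0547 and 0.074). The plasmacytoid dendritic cell list did not pass (2 of 14 higher, or 3 adjusted over the list alone, and 1 lower on both counts, median 0.23, adjusted p = 0.161, adjusted p = 0.433 with an estimated correlation). Ncr1 (0.55 ± 0.22), Cd5l (-0.12 ± 0.25) and Il23r (1.06 ± 0.43) had adjusted p = 0.0958, 0.781 and 0.103. The count of differing genes was 1399 without imiquimod-ear 1, 1653 without imiquimod-ear 3, and 4460 without imiquimod-ear 5. It was 1330, 1670 and 1117 without IL-23-ear 1, 2 and 3, and 1207 with only these groups in the fit.

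The responses were also compared across genes, which are not independent replicates. Log2 fold changes against control after dorsal and ear imiquimod had a Pearson correlation of 0.606 (Spearman 0.688) over 15159 genes, where unchanged groups against the same 3 controls gave 0.575 on average in 20 simulations and at most 0.653. Their covariance was 0.4247 against a simulated 0.0777, a difference of 0.347. Of the called genes, 1702 rose in both and 916 fell in both, where independent lists would share 697.1 and 291.8, and 39 were called in opposite directions. The IL-23 response had a correlation of 0.077 with the dorsal response (simulated 0.538; covariance 0.038 against 0.0782) and of 0.279 with the ear response (simulated 0.547; covariance 0.0749 against 0.0794). All 7 genes called up after IL-23 were also called up after ear imiquimod (1 shared by independent lists). The 3 controls could not be split into parts of at least 2 libraries each, so part of any excess may come from the shared controls.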

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

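The artifact tests and random regroupings below were written after the results they bear on were seen; the comparison of imiquimod at the ear with imiquimod on the back was planned. Among 210 values tested in groups of 4 libraries, 18 had 1 library far from the other 3, where chance gives about 1 in 20.

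Interferon-stimulated genes were lower after imiquimod at both sites. Even dilution by expanding cells other than B cells would lower B cell genes alike. After dorsal treatment the interferon list instead lay below the B cell list, with a median log2 difference of -2.65. The 95% bootstrap interval over genes was -3.55 to -1.91, and after ear treatment the difference was -1.43 (-1.62 to -1.01). Cell groups fell unevenly, with medians of -2.536 for T cell and -0.185 for B cell genes after dorsal treatment. The B cell list thus cannot decide on uneven dilution, on loss of other cells, or if B cells expanded too. At the ear the difference from the T cell list, -1.22 (-1.40 to -0.81), argues against loss of T cells for these genes. At the dorsal site it was -0.30 (-1.25 to 0.46), so the T cell and interferon falls cannot be told apart there. All these intervals resample genes and not mice, so they do not cover the spread between mice and settle no cause. Ear libraries had interferon scores from -2.214 to -0.947 and T cell scores from -0.845 to 0.073. Interferon scores of controls 2, 4 and 5 were -0.792, 0.531 and 0.261, so the controls differed among themselves. Raised interferon genes in the controls alone are argued against by 27 of 29 members that were higher in IL-23-ear than in imiquimod-ear libraries, though those 2 groups also differ in agent, dosing and time. A hypothesis that stays open is that repeated imiquimod may lower interferon signaling in the spleen. The plasmacytoid dendritic cell list, of cells that make interferon, had a median of -0.54 after dorsal (adjusted p = 0.0153, adjusted p = 0.447 with an estimated correlation) and of -0.22 after ear treatment (adjusted p = 0.174). Whether fewer such cells lowered the interferon genes stays open, and the time since the last dose was not tested.

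Erythroid genes were higher after dorsal imiquimod. More residual blood would bring mainly globin RNA. Yet Gata1, Klf1, Tal1 and Epor, genes of nucleated precursors, had a median log2 fold change 1.59 above that of the globin genes. Single precursor genes lay above single globin genes by 0.86 to 2.25, which is a range over these genes and not a confidence interval. A large share of haemoglobin counts is argued against as the whole cause, since 27 of 28 members were still called up with haemoglobin and immunoglobulin genes taken out. The globin copies share reads, so their values are uncertain. More red cell formation in the spleen remains a hypothesis, and blood loss, anaemia and grooming or weight changes were not tested.

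Mitochondrially encoded genes were higher after IL-23. A trend on gene length is argued against as the whole cause, since the list median was 0.23 (adjusted p = 4.95e-10) with the trend removed against 0.33 without, although 0 of its genes then passed in edgeR's test against 4. Haemoglobin counts are argued against by a median of 0.33 (adjusted p = 6.92e-20) with haemoglobin and immunoglobulin genes taken out. RNA quality and tissue handling stay open and may matter, since mitochondrial genes took 3.53% ± 0.07 of the counts (SD, n = 3) against 2.93% ± 0.16 in the controls (n = 3), and the list did not pass with an estimated correlation (adjusted p = 0.146).

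Chance was tested by regrouping the libraries of each comparison. The smallest share that 35 splits can give is 2.9%, and no adjustment was made for the several counts. A real split that ranks first thus argues against chance but cannot exclude it. For imiquimod-dorsal against control 1 of 35 splits, the real one, gave as many genes (9071, highest other 5087), which argues against chance. For the number of lists 21 of 35 did (17, highest other 25), which does not. For imiquimod-ear against control 2 of 35 splits gave as many genes (3219), so chance is not excluded. The highest other was 4934, for the 3 controls with imiquimod-ear 5 against the rest, a structure of the samples. Only 1 of 35, the real one, gave as many lists (24, highest other 22). The margin is narrow, and 0 lists passed with an estimated correlation. For IL-23-ear against control the 10 splits are too few for a share under 0.05. For genes 1 split, the real one, gave as many (8, highest other 1). For lists 8 splits gave as many (8, highest other 15), which does not argue against chance. For imiquimod-ear against imiquimod-dorsal 1 of 35 splits gave as many genes (7237, highest other 1), which argues against chance. By contrast 19 gave as many lists (17, highest other 22), which does not. For IL-23-ear against imiquimod-ear 2 of 35 splits gave as many genes (2623; highest other 4540, imiquimod-ear 1, 3 and 4 against the rest) and 2 as many lists (24; highest other 24), so chance is not excluded for either.

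Imiquimod-ear and imiquimod-dorsal responses differed by a direct test in 7237 genes and in 17 lists. None of the 17 passed with an estimated correlation (adjusted p = 0.495 to 0.674). The list medians of the difference, ear minus dorsal, were 1.28 for type I interferon, 0.72 for interferon gamma, -1.71 for mature neutrophil, 0.81 for conventional and 0.61 for plasmacytoid dendritic cell, -3 for erythroid, -2.49 for heme and -1.28 for cell cycle genes. They were 1.49 for plasma cell, 1.46 for germinal center, 2.16 for T cell, 1.63 for regulatory T cell, 1.29 for NK, 0.63 for MHC class I, 0.23 for MHC class II, 0.66 for unfolded protein response and 0.50 for cholesterol synthesis genes.

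Among dorsal libraries far from the other 3, imiquimod-dorsal 4 had a pancreas score of 7.225, imiquimod-dorsal 2 a conventional dendritic cell score of -1.005 and Cd3e at 26 CPM, and imiquimod-dorsal 3 had S100a8 at 288 and Ighg2b at 319 CPM. Among ear libraries, imiquimod-ear 3 had a mature neutrophil score of -0.178, a neutrophil progenitor score of 0.961, and S100a8 at 16.9, S100a9 at 43.4, Ly6g at 0.977 and Fcnb at 3.25 CPM. Imiquimod-ear 4 had 10.16% of its counts in its 10 highest genes, a pancreas score of 1.442, Mybpc2 at 71 and Tnni2 at 74.5 CPM. Imiquimod-ear 1 had a marginal zone B cell score of 0.177 and imiquimod-ear 5 had mt-Nd3 at 101 CPM. Of 467 unnamed loci outside the main measurement, 55 were higher and 99 lower than in the controls after dorsal imiquimod, and 22 higher and 19 lower after ear imiquimod.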

How the results depend on the processing

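The fits with a length trend removed, and the correlations without a control, were chosen after the results were seen. With a 2-fold minimum, 3002, 630, 0, 2088 and 736 genes passed in the order dorsal, ear and IL-23 against control, ear against dorsal, and IL-23 against ear; the 0 is by edgeR, with 1305 genes at an unadjusted p under 0.05, and the lower counts follow from the minimum. With an estimated correlation 0 lists passed in all 5 comparisons by camera, where fry called 24, 13, 1, 22 and 15. With only the compared groups 1046 genes passed for ear against control, 1 for IL-23 against control and 1207 for IL-23 against ear; fewer samples enter those fits. For IL-23 against control, RLE factors, no filter and the length trend removed left 0 genes, limma-voom called 15 and DESeq2 132; the cause was not tested. The replicate numbers did not pair the libraries: 13 same-numbered pairs had a median correlation of deviations of -0.045 (-0.241 to 0.183), and 2 of 14 libraries correlated best with their own number. With the replicate block, 311 genes passed for ear against control, 0 for IL-23 against control and 1261 for IL-23 against ear, and 13 lists for IL-23 against control. Leaving out 1 replicate gave 8023 to 8781, 1090 to 4976, 0 to 1, 6288 to 7242 and 1117 to 4460 genes, and 16 to 18, 19 to 24, 7 to 11, 16 to 19 and 21 to 25 lists. Correlations of responses were 0.733 for dorsal and ear over genes with log2 CPM of at least 3 and 0.687 over called genes, -0.228 for dorsal and IL-23 and 0.047 for ear and IL-23 over the former; without 1 control they were 0.599 to 0.686, 0.093 to 0.303 and 0.338 to 0.49. Cela2a, -7.99 in ear against dorsal, turned to 3.87 without imiquimod-dorsal 4, the library that held its counts, and was -9.25 without imiquimod-ear 4, and the mitochondrial list in ear against control turned from 0.19 to -0.004 with the length trend removed; the cause was not tested. The share of rises in ear against control was 67.1%, 60.6% with RLE factors and 58.5% with DESeq2. Calls of named genes held without each replicate in 90 of 99, 42 of 67, 0 of 8, 86 of 92 and 56 of 72 cases, and of lists in 16 of 17, 17 of 24, 4 of 8, 16 of 17 and 20 of 24. With only the compared groups, the calls of Isg15 and Siglech were also lost in IL-23 against ear (adjusted p = 0.0501 and 0.0601), of Tnni2 in ear against dorsal (0.0681) and of Cxcl10 in ear against control (0.0649). So were those of the adipose (0.088) and stromal lists (0.0548) in ear against control and of MHC class II genes in ear against dorsal (0.0515). The adipose call in ear against control was lost with RLE factors (0.0665) and with haemoglobin and immunoglobulin genes taken out (0.0606), and that of Cxcl10 with no filter (0.0614). With the replicate block, the calls of Ifit3, Ifit1, Mx2, Trim30c, Gbp4, Cxcl10, Mki67, Pdia4, S100a8, S100a9 and Tlr7 were lost in ear against control, with adjusted p from 0.0515 for Ifit3 to 0.235 for Cxcl10, as were those of Cd3e and Cxcl10 in IL-23 against ear (0.0648 and 0.0542) and of Tnni2 in ear against dorsal (0.0962). Lists that passed with the block and not without it were cell cycle (0.00377), cholesterol synthesis (7.14e-05), complement (0.0207) and pancreas genes (0.0207) in IL-23 against control, and megakaryocyte genes (0.048) in ear against dorsal. Stromal genes passed in ear against dorsal with the block (0.0469) and with no filter (0.0472), and adipose genes in IL-23 against ear with the block (0.00707) and with only these groups (0.0135). Heme (0.0465) and pancreas genes (0.0486) passed in IL-23 against control with only these groups, and complement genes in ear against control with the length trend removed (0.0336). By DESeq2, Isg15, Ly6g and Ncr1 passed in ear against control (0.0465, 0.028 and 0.0498) and Cd5l in ear against dorsal (0.0343), which edgeR did not call.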

Other observations

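The counts in the next paragraph were chosen after the values of single genes were seen. They are of a gene group that no list had been fixed for.

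Genes of cytosolic ribosomal proteins, 78 in all, had a median above that of the controls in each treated group. After dorsal imiquimod 64 passed as higher and 1 as lower by edgeR's test, with a median log2 fold change of 0.29 over the 78. After ear imiquimod 66 passed as higher, with a median of 0.32. After IL-23 the median was also 0.29, with 77 of 78 higher, but only 3 passed. With RLE factors the medians were 0.27, 0.29 and 0.28, and with the length trend removed 0.25, 0.28 and 0.24. The treated groups share the same 3 controls, so the controls' own chance values enter all of these medians, and processed copies share reads with these genes. Compared directly, the median was 0.03 for ear against dorsal imiquimod and -0.02 for IL-23 against ear imiquimod. The treated groups thus hardly differed from each other in these genes.

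Some transcripts stood out in 1 library. Imiquimod-dorsal 4 held the pancreatic enzyme genes Ctrb1 at 94.8, Cela2a at 52.1, Try4 at 47, Pnlip at 42.6 and Prss2 at 31.7 CPM, where the next highest library had at most 1.17 CPM of any of them. Control 5 had the highest values of the fat cell genes Car3 at 24.9, Cfd at 17 and Adipoq at 4.32 CPM, against at most 9.54, 2.72 and 1.5 CPM elsewhere. IL-23-ear 3 held the heat shock genes Hspa1b at 151, Hspa1a at 106 and Hsph1 at 899 CPM, against at most 19.4, 14.2 and 323 CPM elsewhere. Control 2 had Ifit2 at 1.98 CPM, the lowest of the 14 libraries, whose median was 27.3 CPM. Controls 4 and 5 had it at 192 and 138 CPM, and the imiquimod libraries at 13.6 to 47.3 CPM. For this interferon-stimulated gene control 2 thus lay below every imiquimod library.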
